A study of Lactiplantibacillus plantarum with 2 samples.

How the data were processed

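Gene expression was measured on 2 two-colour DNA microarrays, each comparing a lactate-treated sub-culture with an untreated one of a mutant of Lactiplantibacillus plantarum, a lactic acid bacterium. Per the labels, the treated RNA carried Cy5 and the untreated RNA carried Cy3 on both arrays, so no dye swap was present. Both arrays used the same untreated sub-culture, and the series states that no biological replicates were made. With 1 array per comparison, no test, standard error or p-value was computed, and every difference lacks a replicate check.

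The deposited spot intensity values of both channels came from the ImaGene image quantification software, per the file headers. They were used as raw mean signals and median local backgrounds on a linear scale. The authors also deposited 1 table of processed values, which matched the log2 ratio of Cy5 over Cy3 of the same spots. Its correlation with the ratios computed here was 0.994 for the L-lactate array and 0.987 for the DL-lactate array. Its scale and direction were read from this match, and its column medians were -0.02 and -0.01. How it was normalized is not given in the sources used here, beyond the name limma in the submitters' processing notes, where no version is given. It was used as an alternative only. It held 9606 values per array, and the single spot of lp_0537 had none.

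Each array had 10807 spots, of which 1200 were controls or blanks and 9607 were bacterial spots. Of these, 9553 spots carried locus tags and belonged to 7968 probes of 2851 genes. The remaining 54 spots were other features and entered no count. There were 3 probes for 2442 genes, 2 probes for 233 genes and 1 probe for 176 genes.

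Background was corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50. Each array was then normalized by loess, with control spots at weight 0. The 2 arrays were put on a common intensity scale by quantile normalization of the average intensities, which leaves ratios as they are. Spots of one probe were averaged, and a gene's value was the median over its probes, given with the SD over probes. That SD covers the spread within 1 array only. The difference between treatments was the L-lactate ratio minus the DL-lactate ratio per probe, again with the median over probes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

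In place of a test, a fixed size rule was used. A gene was called higher or lower when its value reached 2-fold (log2 of 1 or more in size), when every probe had the same sign, and when at least 1 probe was well above background in at least 1 channel. A spot was well above background when its mean signal exceeded the mean local background by more than 2.6 background SDs. L-lactate-specific genes passed the rule with L-lactate and, in the same direction, in the difference between treatments. Calls by this rule are sizes on these arrays, not tested changes.

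The normalization, the size rule, the rule for named genes, the 2 locus-tag lists for the lactate racemase operon and its upstream region, and most alternatives were chosen before the data were examined. Named genes were every gene of those 2 lists, the lactate dehydrogenase genes ldhL1, ldhL2 and ldhD, the 10 highest and 10 lowest genes past the rule with 2 or more probes in each comparison, and up to 4 members of each list past the rule. The files do not pair locus tags with gene symbols. The reference gene table, of assembly ASM991365v1 from another strain with 3031 genes, matched 0 of the 2851 locus tags. For that reason 26 lists defined by symbol or product gave no members and were not run. In their place 20 blocks of neighbouring locus tags were written down from general knowledge of the reference strain WCFS1, and likewise the tags of the 3 dehydrogenase genes. These blocks were chosen after the identifiers and a few spot values had been seen, among them low ratios next to the pyrimidine block, and before gene values were computed. Locus tags identify genes here, and functions given for them are background knowledge that the files do not state. Because functions were not paired with tags, few tags outside the lists are printed.

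For each list, the median of its members was set against 10000 random lists of the same size, matched on mean intensity. The resulting percentile describes these 2 arrays and is not a test. Random members were drawn independently, whereas neighbouring genes tended to pass the size rule together. Percentiles can therefore overstate how unusual a block of neighbours is.

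The quantification software marked 147 locus-tag spots on the L-lactate array and 356 on the DL-lactate array. On the DL-lactate array these marks fell on 20.3% of the spots in the top intensity decile. Marked spots were kept, because leaving them out would remove bright genes selectively and because their ratios were close to those of unmarked repeats. On the L-lactate array the SD between repeat spots (log2) was 0.11 with 1 spot marked, over 52 pairs, and 0.10 with none. On the DL-lactate array it was 0.09 with 1 spot marked, over 78 pairs, and 0.08 with none. Marked spots without an unmarked repeat were not compared. Keeping the marked spots was chosen after seeing the data, including calls without them. Leaving them out is given as an added alternative. Counting only genes with 2 or more probes was also added.

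The steps were tested on simulated data made from the intensities of the L-lactate array over 2851 genes. The rule called 0 of 50 genes changed 1.5-fold, 8 of 50 changed 2-fold, 47 of 50 changed 3-fold and 50 of 50 changed 8-fold. It called 0 of 2651 unchanged genes. The simulated noise was independent from spot to spot, with no added spread between probes of a gene or between cultures. These counts are thus no error rate for the real arrays, whose untreated channels differed by 2-fold or more for 15 genes. The offset compressed ratios, so that genes changed 8-fold had a median log2 value of 2.84.

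Other settings covered background correction, normalization within and between arrays, filters on dim or saturated spots, the summary over probes, the fold threshold, the sign rule and the authors' table. Processed signals from the scanner software, listed as a further alternative, were not used here because the files read held none.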

Results

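The strain studied, TF101, is a mutant of L. plantarum NCIMB8826 that lacks NAD-dependent L-lactate dehydrogenase activity and makes no L-lactate of its own. It was grown in MRS, a rich medium for lactobacilli, at 28 °C to an optical density of 0.75 and split into 3 sub-cultures. One received 200 mM sodium L-lactate, one received 100 mM of each of the mirror-image forms D- and L-lactate, and one was left untreated. RNA was taken 1 h 30 min later. The question posed by the design was which genes responded to L-lactate and not to the DL mixture. There was 1 array for each treatment against the untreated sub-culture, so values below are log2 ratios of treated over untreated, with the SD over the probes of a gene. The number of arrays limits the precision, and no difference could be tested.

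Both arrays measured nearly every gene above background. Median spot intensities were 1037 (Cy3) and 956 (Cy5) on the L-lactate array, against local backgrounds of 479 and 476. On the DL-lactate array they were 1053 and 956, against 479 and 477. Between 98.4% and 100.0% of locus-tag spots were well above background in a given channel, compared with 0 to 2 of the 89 negative-control spots. No named gene was below background on all of its probes in any channel.

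With L-lactate, the genes of the lactate racemase operon were the highest on the array. The racemase interconverts D- and L-lactate, and several of the genes that follow it serve the synthesis of its nickel-containing cofactor. All 5 measured members of the operon passed the size rule, with a median log2 ratio of 5.36, or 41.1-fold above the untreated sub-culture. Without background subtraction the operon median was 4.28, and with the authors' processed values it was 5.86. lp_0104, the first gene of the list, stood at 5.72 ± 0.71 (SD, n = 3 probes), and lp_0109, the last, at 5.78 ± 0.25. lp_0105, lp_0106 and lp_0107 stood at 5.36 ± 0.54, 4.97 ± 0.54 and 5.06 ± 1.33. The 4 measured genes just upstream, a group of regulator and transporter genes, were also higher, with a median of 3.30 or 9.84-fold. Their values were 2.42 ± 0.26 for lp_0100, 3.85 ± 0.54 for lp_0101, 3.00 ± 0.67 for lp_0102 and 3.59 ± 1.01 for lp_0103. The medians of both lists lay above all 10000 matched random lists. The listed tags lp_0099 and lp_0108 were not analysed here.

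**Figure D1:**
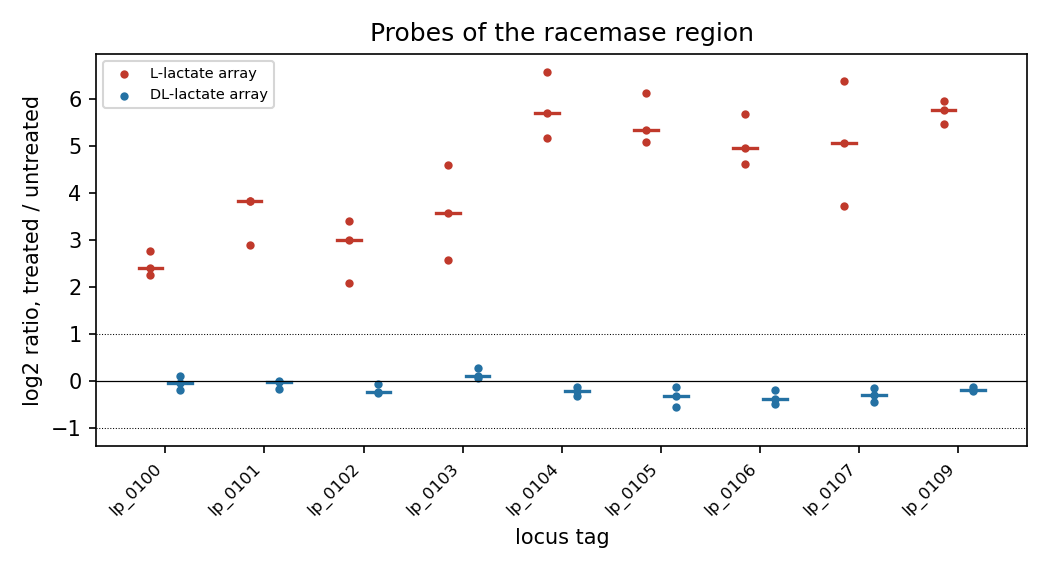
Log2 ratio of treated over untreated (vertical axis) for each probe of the 9 measured genes of the racemase operon and its upstream region (horizontal axis, locus tags in order), with points for probes, short bars for gene medians and dotted lines at 2-fold. On the L-lactate array the gene medians run from 2.42 to 5.78, and on the DL-lactate array from -0.37 to 0.11.

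A block of fatty acid synthesis and acetyl-CoA carboxylase genes, lp_1670 to lp_1682, was the other large group above untreated with L-lactate. All 12 measured members passed the rule, between 1.63 and 3.39, with a median of 2.92 or 7.59-fold. Without background subtraction the block's median was 2.24. Its highest members were lp_1674 at 3.39 ± 0.93 and lp_1670 at 3.23 ± 0.33. In all, 45 genes were higher and 63 lower with L-lactate out of 2851, and 9 of the 45 belonged to the racemase region and 12 to the fatty acid block. Without background subtraction 30 genes were higher and 24 lower, and the median of the upstream genes was 2.17.

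The 5 lowest values with L-lactate were those of lp_0822, at -2.97 ± 0.27, and of 4 neighbouring genes of the pyrimidine nucleotide synthesis block. lp_2697 to lp_2700 lay between -3.23 and -2.71, whereas lp_2702, lp_2703 and lp_2704 of the same block were at -0.47 ± 0.37, 0.30 ± 0.35 and 0.22 ± 0.12. The 4 citrate lyase genes lp_1106 to lp_1109 were all lower, with a median of -1.73 or 3.32-fold. Without background subtraction their median was -0.96 and 1 of the 4 passed the rule. In the block of the pyruvate dehydrogenase complex, which makes acetyl-CoA from pyruvate, 2 of 4 genes were lower with L-lactate, lp_2154 at -1.32 ± 0.06 and lp_2153 at -1.15 ± 0.15, and 1 of the 4 passed without background subtraction. The second L-lactate dehydrogenase gene, ldhL2 (lp_1101), stood at -2.44 on its single probe, and at -1.44 without background subtraction. The genes ldhL1 (lp_0537) and ldhD (lp_2057), for the L- and D-lactate dehydrogenases, were at 0.14 (1 probe) and -0.01 ± 0.50 (2 probes). Probes of ldhL1 give no check of the mutation, since the part of the gene that is altered is not given in the sources used here.

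With DL-lactate, the racemase region was close to the untreated level. The operon had a median log2 ratio of -0.28 and the upstream genes one of -0.02, and 0 of the 9 genes passed the size rule. The operon median was at the 4.39th percentile of matched random lists, and that of the upstream genes at the 45.7th. Without normalization between the dyes the operon median was -0.64, on an array where the median of all genes was then -0.30. L-lactate itself was added to this sub-culture at 100 mM.

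The fatty acid block was also high with DL-lactate, with all 12 measured members past the rule and a median of 2.82 or 7.06-fold. Without background subtraction 11 members passed and the block's median was 2.19. Its ratios with L-lactate exceeded those with DL-lactate by a median of 0.24 and at most 0.61, above all 10000 matched random lists, or by a median of 0.085 with median centring, and 0 of the 12 genes passed the rule in this difference. Such small shifts were not particular to this block. The ribosomal protein cluster (0.34, percentile 100) and the purine block (0.20, percentile 99.98) had them too, while the pyruvate dehydrogenase and second prophage blocks lay at the other end, both at a percentile of 0.02. lp_1670 was the highest gene on the DL-lactate array at 3.24 ± 0.23. The pyrimidine block was lower along its whole measured length with DL-lactate. All 7 measured genes passed the rule, from -4.44 ± 0.13 for lp_2697 to -1.87 ± 0.10 for lp_2704, with a median of -4.18 or 18.2-fold. The 4 citrate lyase genes were lower with a median of -1.58 (2 of 4 past the rule without background subtraction), and ldhL2 stood at -2.38 (1 probe), or -1.55 without background subtraction. ldhL1 was at 0.23 (1 probe) and ldhD at 0.10 ± 0.47 (2 probes). In the third capsular polysaccharide block, 4 of 9 genes were lower with DL-lactate, led by lp_1224 at -1.42 ± 0.16, and 0 of 9 with L-lactate. Without background subtraction, 0 of the 9 passed the rule with DL-lactate. In the difference between treatments 0 of the 9 passed, with a median of 0.32 and at most 0.64. In all, 43 genes were higher and 51 lower with DL-lactate. Without normalization within the array the split was 32 higher and 82 lower, and with median centring it was 62 higher and 47 lower. Without background subtraction 23 genes were higher and 31 lower.

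The difference between the treatments compared sub-cultures that were given the same total amount of added lactate in different mirror-image forms. Lactate made by the cells themselves was not measured here. It was largest in the racemase operon, where the L-lactate ratio exceeded the DL-lactate ratio by a median log2 value of 5.68, or 51.2-fold. For the upstream genes the median difference was 3.35, or 10.2-fold. Without background subtraction the operon and upstream differences were 4.43 and 2.20. With the authors' processed values the operon difference was 6.18. The next group was the pyrimidine block, whose 7 measured genes all had higher ratios with L-lactate than with DL-lactate. The difference was 3.05 ± 0.26 for lp_2702, 2.83 ± 1.03 for lp_2703 and 2.09 ± 0.22 for lp_2704, and between 1.09 and 1.62 for lp_2697 to lp_2700. Together 22 genes passed the rule with the higher ratio in L-lactate, 9 of them in the racemase region, 7 in the pyrimidine block and 6 elsewhere. Only lp_2780, at -1.34 ± 0.21, and lp_0175, at -1.24 ± 0.06, passed it in the opposite direction. Without background subtraction 16 genes were higher, with 5 of the 7 pyrimidine genes past the rule, and with median centring 25 were higher and 12 lower, with 6 of the 7. The count of lower genes was also 6 with background subtracted without normexp, 6 without normalization within the array, 7 with the authors' processed values and 16 when the Cy5 channels were compared directly. In that direct comparison lp_2697, lp_2698 and lp_2699 were just short of 2-fold, at 0.85, 0.96 and 0.99.

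**Figure D2:**
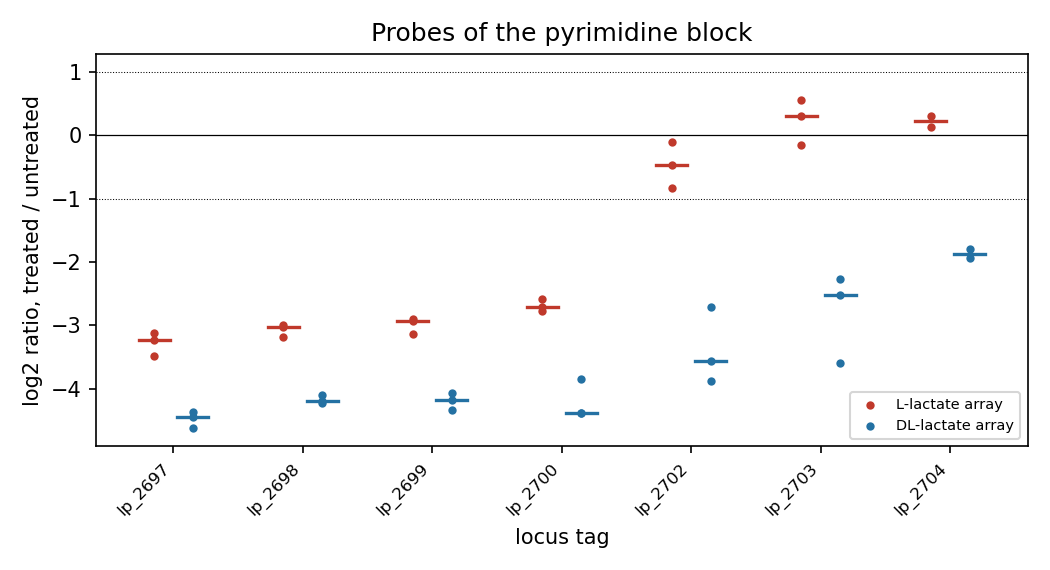
Log2 ratio of treated over untreated (vertical axis) for each probe of the 7 measured genes of the pyrimidine block (horizontal axis, locus tags in order), with points for probes, short bars for gene medians and dotted lines at 2-fold. On the DL-lactate array all medians lie at or below -1.87, while on the L-lactate array lp_2702, lp_2703 and lp_2704 lie between -0.47 and 0.30.

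By the fixed definition, 13 genes were L-lactate-specific, 11 higher and 2 lower. The 11 were the 9 measured genes of the racemase region, lp_3154 at 1.26 and lp_2716 at 1.34, the last on a single probe. Both were near the untreated level with DL-lactate, at -0.07 and -0.01. The 2 lower genes were lp_2780, at -2.37 with L-lactate and -0.76 with DL-lactate, and lp_0175, at -1.19 and 0.03. The DL-lactate value of lp_2780 was -0.15 with median centring and -0.36 with the marked spots left out. Without background subtraction 9 genes were higher, all of the racemase region, so lp_3154 and lp_2716 did not pass there. At 3-fold the same 9 were left. The count of lower genes was 9 with median centring in place of loess, 6 without normalization within the array and 10 when the Cy5 channels were compared directly. lp_3154 and lp_2716 lie outside the rule for named genes and were named after their values were seen.

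Most genes had log2 ratios of the same sign on the 2 arrays, which the shared untreated sub-culture favours by itself. Across genes the log2 ratios had a Pearson correlation of 0.72 and a Spearman correlation of 0.78, and genes are not independent replicates. Without the racemase region the Pearson correlation was 0.85. There were 27 genes higher and 35 lower on both arrays, and 0 genes had opposite calls. Without background subtraction 17 were higher and 13 lower on both. Independent lists of the same lengths would share 0.68 and 1.13 genes. Because both ratios used the same untreated sub-culture, 2 unchanged sub-cultures were simulated against a shared one, which gave a mean correlation of 0.40 and a mean covariance of 0.03, against an observed covariance of 0.17. The share of genes with the same sign was 79.0%, compared with 63.1% in the simulation. The simulated values follow from the SDs it was given, 0.19 between sub-cultures and 0.13 for measurement (log2). It held no changed genes, so strongly changed genes shared by both arrays would exceed it in any case. No conclusion is drawn from the gap. Part of the excess may still come from the shared untreated sub-culture, which could not be split.

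**Figure D3:**
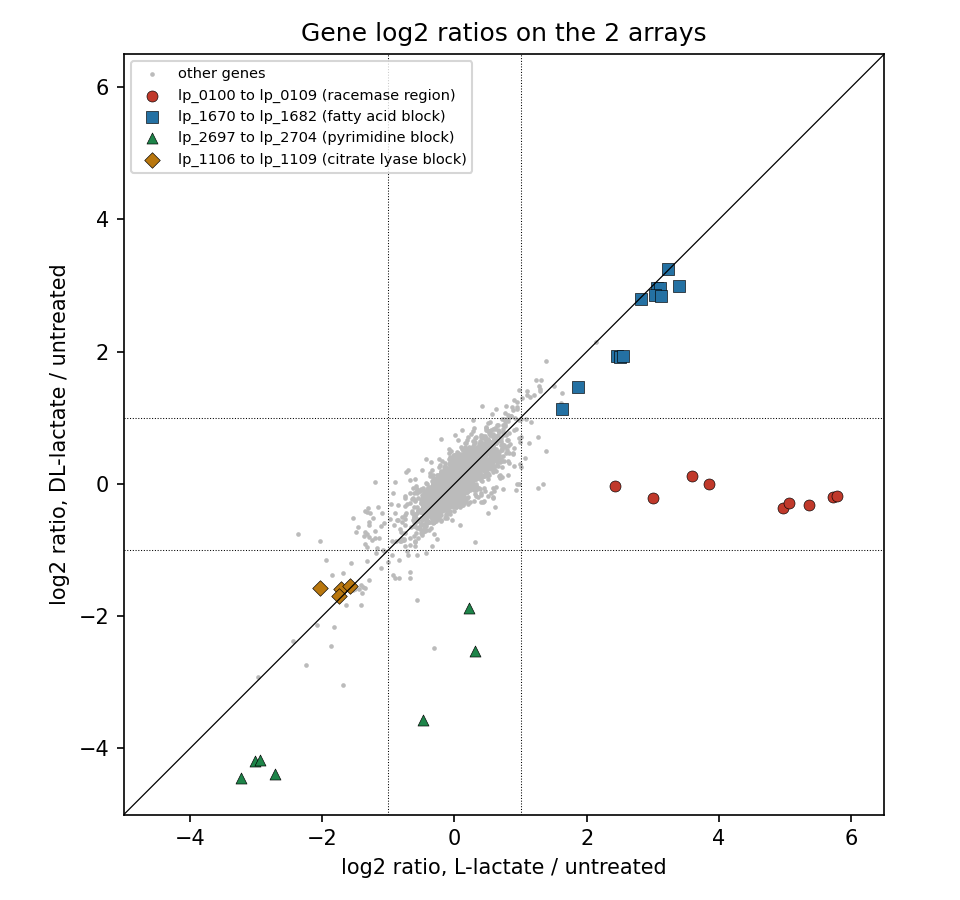
Log2 ratio with DL-lactate (vertical axis) against log2 ratio with L-lactate (horizontal axis) for 2851 genes, with the diagonal of equal ratios and dotted lines at 2-fold. The 12 fatty acid genes lie near the diagonal, the 9 genes of the racemase region lie far to the right near 0 on the vertical axis, and the 7 pyrimidine genes lie below the diagonal.

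All 11 genes of the purine synthesis block were below 0 on both arrays and 0 passed the rule, with medians of -0.46 with L-lactate and -0.66 with DL-lactate, below all matched random lists. Without background subtraction these medians were -0.19 and -0.27. The ribosomal protein cluster had medians of 0.65 and 0.32, at the 100th and 99.0th percentiles, with 1 of 28 genes, lp_1063, past the rule on both arrays at 1.62 ± 0.16 and 1.37 ± 0.03. With median centring its DL-lactate median was 0.73 and 5 of 28 genes passed on each array. Uptake genes for glycine betaine and related osmoprotectants, solutes that cells take up under high salt, had medians of 0.76 and 0.78, at the 97.4th and 98.6th percentiles, with 0 of 3 genes past the rule.

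The dnaK chaperone block was at 0.68 and 0.35, at percentiles of 98.1 and 88.6, and the ATP synthase block at 0.48 and 0.36, at the 95.9th and 95.5th. The groESL chaperonin genes, at 0.29 and 0.24, did not stand apart from matched random lists, at the 65.8th and 67.7th percentiles. With median centring the DL-lactate medians of the 3 blocks, in this order, were 0.58, 0.70 and 0.55. The central glycolysis block was at 0.53 and 0.51, at the 92.0th and 97.2nd percentiles, with 1 of 5 genes past the rule with DL-lactate, lp_0789 at 1.23 ± 0.51. Its DL-lactate median moved with the processing, to 0.98 with median centring and to 0.23 with the marked spots left out, where lp_0789 had no value. The pyruvate dehydrogenase block had medians of -1.03 with L-lactate and -0.38 with DL-lactate, at percentiles of 0.11 and 2.99. With median centring the DL-lactate median was -0.24. In the difference the median was -0.60, at a percentile of 0.02. There 0 of 4 genes passed the rule, or 2 of 4 with median centring.

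The capsular polysaccharide blocks had medians of -0.24 and -0.42 for the first, -0.10 and -0.03 for the second, -0.67 and -0.94 for the third and -0.18 and -0.33 for the fourth. The percentiles, in the same order, were 1.88, 17.9, 0 and 1.33 with L-lactate and 0.12, 44.2, 0 and 0 with DL-lactate. Without background subtraction the third was at -0.33 and -0.43, and the fourth at -0.10 with DL-lactate. The plantaricin bacteriocin block was at -0.16 and -0.15, at percentiles of 2.05 and 2.95. Percentiles between 28.5 and 51.7 were found for the teichoic acid D-alanylation genes at 0.10 and 0.06 and the mannose uptake system at -0.11 and -0.03. The first prophage region was at -0.12 and -0.06, at percentiles of 3.8 and 27.4. The second was at -0.17 and 0.00, at percentiles of 0.01 and 76.5, and in the difference at -0.13, at a percentile of 0.02. The median difference was 0.05 without normalization within the array and 0.02 when the Cy5 channels were compared directly. In these regions 0 of 34 and 0 of 51 genes passed the rule on either array.

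The Cy3 channels of the 2 arrays, which held the same untreated sub-culture, gave the only repeat measurement. The sources used here do not say whether this RNA was labelled once or separately for each array. Per gene they differed with an SD of 0.26 on the log2 scale and a correlation of 0.98, and 15 genes differed by 2-fold or more. Repeat spots of a probe had an SD of 0.10 on the L-lactate array and 0.08 on the DL-lactate array. Probes of a gene differed more, with a pooled SD of 0.24 and 0.20. The differences in the racemase operon and in lp_2702 to lp_2704 were all larger than these spreads, which do not include variation between cultures.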

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

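All tests in this part were chosen after the results they bear on had been seen. For 8 named genes past the size rule in the difference between treatments, every probe had one sign with L-lactate and the opposite sign with DL-lactate. The difference was not tested, because each treatment had 1 array. The log2 differences, L-lactate minus DL-lactate, were 3.22 for lp_0102, 5.84 for lp_0104, 5.68 for lp_0105, 5.34 for lp_0106, 5.35 for lp_0107 and 5.90 for lp_0109, all in the racemase region. The others were 2.09 for lp_2704 of the pyrimidine block and -1.24 for lp_0175. Values of the racemase genes with DL-lactate were within 2-fold of the untreated level, so the opposite sign by itself is a small part of each difference.

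The high ratios of the racemase region on the L-lactate array could come from dye effects tied to these sequences. Such an effect would also appear on the DL-lactate array, which had the same dyes, but the median log2 ratio there was -0.20. Background correction of dim untreated signals could inflate the ratios, yet the lowest median of the region over the settings that change the values was 4.22. Without background subtraction the operon and upstream medians fell from 5.36 and 3.30 to 4.28 and 2.17. The size of the ratios thus depended on this step. A response to the L form of lactate, or to its excess over the D form, remains open as a hypothesis. The added doses of L-lactate also differed, at 200 and 100 mM, and no sub-culture given D-lactate alone was analysed here.

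The fatty acid block was high on both arrays. Dye effects acting on single probes could raise a ratio on both arrays, which had the same dye orientation. They would leave the block near the share of all probes that were 2-fold up on both, 1.02%, but 91.2% of its probes were. However, all 12 gene medians were already known to be past 2-fold on both arrays, so a high share was set in advance. The 1.02% also includes the block's own probes. This comparison therefore cannot decide the question, and no conclusion is drawn from it. A dye effect common to the whole block was not tested. Lactate, the added sodium and a difference in the untreated sub-culture itself were common to both arrays, and no value here separates them.

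The genes lp_2702 to lp_2704 were low with DL-lactate and not with L-lactate, while lp_2697 to lp_2700 of the same block were low with both. A difference between the untreated channels could produce this, but the Cy5 channels alone differed by at least 1.72 on the log2 scale for each of the 3 genes. Spots marked as poor by the quantification software could also produce it, but the smallest difference without them was 2.09. A treatment effect on only part of the block, or a change in 1 sub-culture unrelated to the form of lactate, remains open. No replicate culture was there to tell these apart.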

How the results depend on the processing

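No paired analysis was possible because each treatment had 1 array and no test was made. Of the genes past the size rule, 0 had the opposite sign under any setting that changed the values. The racemase operon stayed between 4.28 and 5.86 (median log2) with L-lactate. Between-array quantile normalization leaves ratios as they are by construction. Leaving out spots marked as poor, and counting only genes with 2 or more probes, were added after seeing the data and moved no count of the main comparisons by over 1.5 times. Without the marked spots lp_0789 had no DL-lactate value, and the glycolysis block median there was 0.23, against 0.98 with median centring. Of 740 medians of the other lists 92 moved by over 1 SD of the members, and 264 of 1802 values of named genes moved by over 1 SD of the probes (the pooled SD for genes with 1 probe). The cause of the changes below was not tested, except that the thresholds and definitions act by construction.

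Without background subtraction, 30 genes were higher and 24 lower with L-lactate, 23 higher and 31 lower with DL-lactate, and 17 higher and 13 lower with both. The operon medians were then 4.28 with L-lactate, -0.070 with DL-lactate and 4.43 in the difference, the upstream medians 2.17 and 2.20 with L-lactate and in the difference, and the Cy3 SD 0.16. With background subtracted without normexp, 6 genes were lower in the difference, and the operon was at 5.81 with L-lactate and 6.18 in the difference. An offset of 16 put the operon difference at 6.08. The authors' processed values gave 7 lower genes in the difference and operon medians of 5.86 and 6.18.

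Median centring gave 12 lower genes in the difference, 9 lower L-lactate-specific genes and a correlation of 0.70. Without normalization within the array, 82 genes were lower with DL-lactate, 6 in the difference and 6 among the L-lactate-specific genes. The correlation was 0.70, the same-sign share 87.2%, the operon medians -0.64 with DL-lactate and 6.03 in the difference, and the upstream median -0.41 with DL-lactate. The Cy5 channels compared directly gave 16 lower genes in the difference, 10 lower L-lactate-specific genes and an operon difference of 6.06, and 20 of the 24 genes in the difference were kept.

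At 1.5-fold, 156 genes were higher and 137 lower with L-lactate, 149 and 122 with DL-lactate, 46 and 33 in the difference, 23 and 24 as L-lactate-specific, and 90 and 86 with both. At 3-fold the counts were 24 and 20 with L-lactate, 12 and 22 with DL-lactate, 14 and 0 in the difference and 11 and 13 with both, with 0 lower L-lactate-specific genes. Defining L-lactate-specific genes as under 1.5-fold with DL-lactate gave 10 lower genes, and as under 2-fold gave 18 higher and 28 lower genes. At least 98.4% of spots were well above background, and leaving out that filter changed no call. Background subtraction did change calls. Without it, 54 of the 108 calls were kept with L-lactate and 54 of the 94 with DL-lactate.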

Other observations

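All tests in this part were chosen after the results had been seen. The racemase run with L-lactate reached lp_0111, as 10 neighbours with a lowest value of 1.00. The pyrimidine run began at lp_2696 on both arrays. Further runs of at least 3 neighbouring measured locus tags passed the size rule together, and not all are printed. With L-lactate, lp_0172 to lp_0175 were lower as 4 neighbours with a median log2 ratio of -1.27, against -0.44 with DL-lactate. The 4 neighbours lp_2648 to lp_2651 were lower with a median of -1.23, against -0.68 with DL-lactate. Among the genes from lp_0172 to lp_0175 and from lp_2648 to lp_2651, only lp_0175 passed the rule in the difference between treatments. The medians of lp_0230 to lp_0233, a run with L-lactate, were -1.46 with L-lactate and -1.08 with DL-lactate. Those of lp_0168 to lp_0170, lower with both treatments, were -1.35 and -1.58. The 7 neighbours lp_1105 to lp_1113, which hold the citrate lyase genes, were lower with both treatments, with medians of -1.72 and -1.58. With DL-lactate, the 4 neighbours lp_0927 to lp_0930 were higher with a median of 1.36, against 1.00 with L-lactate. These runs were picked from the values, and their functions are not paired with the tags in the files.

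If ratios past the rule came from independent noise of probes, genes past it would be scattered along the chromosome. With L-lactate, 55 adjacent pairs of locus tags passed in the same direction, against a mean of 2.02 and a highest count of 8 in 10000 shuffles. With DL-lactate there were 41 such pairs, against a mean of 1.53 and a highest count of 8. The pairs include those within the large runs already described. The counts therefore do not show whether called genes outside these runs are noise. The clustering may reflect transcription in operons, which stays a hypothesis. It says nothing about variation between cultures, which would also act on whole operons.

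Among the 54 spots of other features, no feature reached a median of 2-fold above untreated on either array. The feature named SRP had values of -0.88 and -0.98 on its single spot.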
